A study of Strongylocentrotus purpuratus with 8 samples.

How the data were processed

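RNA from SpRunt-1 morphants of 4 cultures was set against 1 pool of RNA from untreated embryos on 8 two-colour Agilent arrays, per the labels, with the morphant in Cy5 on 4 arrays and in Cy3 on the other 4, which hold the same RNAs. Total RNA was extracted with a column kit and amplified into labelled RNA from oligo dT, per the labels' protocols. The authors' scanner files were made with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. Per the file headers they give for each spot a mean signal intensity and a local background intensity in each channel, neither normalized. They also give, per the file headers, intensities that the software had background-subtracted and dye-normalized, and the log10 ratio of Cy5 over Cy3 that it made from those. The authors' deposited value table holds log2 ratios per spot. Set against the scanner values, its columns correlated at 0.971 to 0.993 with loess-normalized ratios of the unsubtracted signals, all already turned to morphant over control, and their medians were 0.000503 to 0.0248; the steps that made the table are not given in the sources used here. No genome build is involved. The identifiers of this array were not matched to the RefSeq gene table of assembly Spur_5.0, so genes are named as the array files name them, and many of those names are shortened.

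Everything else was computed here in R 4.3.3 with limma 3.58.1, and files were read with the data.table package in version 1.17.8. Mean signals were corrected with normexp (offset 50) using the median local background, and each array was normalized by loess with its 536 control spots at weight 0. Ratios were turned to morphant over control, spots marked as outliers by the scanner software (0 to 32 per array) were left out, and the 2 arrays of a culture were averaged, so that n = 4 and a dye effect cancels. The array holds 12696 probes for 6414 targets, 6282 of them with 2 probes. A probe was kept if it was well above background in at least 1 channel on at least 4 of the 8 arrays, which left 9563 probes. A gene with several kept probes was represented by the brightest. For the 4082 genes with 2 kept probes the ratios of both correlated at 0.753 across genes, and 21.3% had opposite signs. Between 60.8% and 77.1% of probes per array were well above background in Cy3 and between 51.5% and 79.5% in Cy5, and 3 to 80 were saturated. No changed gene was below background or saturated on all arrays in a channel.

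The mean log2 ratio of a gene was tested against 0 with lmFit and eBayes and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Intervals are limma's moderated 95% intervals, and errors are SDs between cultures. A loess-normalized ratio is relative to the other genes of the array at its brightness, so a change shared by most genes would not be seen. Differences between cultures were tested with an F test on all 8 arrays with a term for the dye. The 24 gene lists were Runx and partners, earlier reported Runt-1 targets, Wnt signalling, cell cycle, Akt, PI3K, TOR and PKC signalling, apoptosis and DNA damage, endomesoderm regulators, skeletogenic cells, pigment and blastocoelar cells, oral ectoderm, aboral ectoderm, neurogenic and apical plate genes, cilia, early blastula, late blastula to gastrula, histones, ribosomal proteins, mitochondrial respiration, proteasome and ubiquitin, heat shock, stress and xenobiotic genes, RNA splicing, extracellular matrix and adhesion, transposable elements, and actin cytoskeleton. Members were found by symbol or by a pattern in the name, which misses shortened names and takes in a few chance matches. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, whose directional test asks whether the genes of a list move one way on balance without comparing them with other genes.

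The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the probes of Runt, the 10 largest rises and 10 largest falls among named genes that passed with 1 sign in all cultures and both dye orientations, up to 4 passing members of each list with the smallest p (or 1 or 2 that did not pass where none did), the earlier reported targets and akt. A target counted as named if its name had at least 3 letters and was not an identifier, a word for an unknown product or 1 word followed by protein, which left SPAN protein out of the 10 largest rises although it has a name. The alternatives were other background corrections, Agilent's own log ratio, median centring without loess, quantile scaling of average intensities, no filter or a stricter one, the authors' table, the dye-swap arrays as a random block or 1 orientation alone, each culture left out, the mean of a gene's probes, all probes tested separately, a variance trend with robust eBayes, other thresholds, and the other list tests. Lists completed with shortened names were added after seeing the data.

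The code was tested on simulated arrays of the same 5481 genes, of which 67 were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. With the spread between cultures of the real data the test found 32.8%, 70.1% and 95.5% of them, with 11 unchanged genes among 143 called. The median estimate for a true log2 change of 1 was 0.86. The change was set on signals that already held the offset, so this value does not measure how far the offset pulls ratios towards 0. The F test, on 5439 genes, found 72.3%, 90.8% and 100% of genes whose SD between cultures was 1.5-fold, 2-fold and 4-fold. Of 22 simulated lists camera called 0 with no shift and 21 with a shift of 0.25, and with an estimated correlation 0 and 3. The simulated genes varied independently and the shift was added after normalization. Real members can move together, so these counts do not tell how large a shift camera could miss in the real lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.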

Results

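Gene expression was measured in hatched blastulae of the purple sea urchin Strongylocentrotus purpuratus whose zygotes had been injected with a splice-blocking morpholino against SpRunt-1. A morpholino is a synthetic oligonucleotide that binds RNA, here at a splice site, and SpRunt-1 encodes a transcription factor of the Runx family. The 4 morphant samples came from 4 cultures with different parents, with 3600 embryos and about 5 µg of RNA per sample. The control was 1 pool of RNA from about 14400 untreated embryos of the same cultures. All embryos were collected 18 hours after fertilization at 15 °C. Each morphant RNA was hybridized against the pool on 2 arrays with the dyes exchanged, which gave 8 two-colour arrays and n = 4 cultures. Of 6414 targets on the array, 5481 were bright enough to be tested. Median signals per array were 66.4 to 86.6 in Cy3 and 59.9 to 95.5 in Cy5 over local backgrounds of 44 to 51. The number of arrays, from only 4 cultures, limits the precision, and the median SD of a gene between cultures was 0.239 on the log2 scale.

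The first comparison asked whether the Runt transcript itself differed in the morphants. Its brighter probe (CUST_8630) had a mean log2 ratio of morphant over control of −0.18 ± 0.27 (SD, n = 4), or 0.885-fold, with culture values of −0.21, −0.54, −0.04 and 0.09. The 95% confidence interval ran from −0.50 to 0.15 and the limma adjusted p was 0.345, so the difference was within the spread between cultures. The dimmer probe (CUST_8629) gave −0.20 ± 0.09 (SD, n = 4), below 0 in all 4 cultures, with an interval of −0.36 to −0.03 and an adjusted p of 0.119 among all probes. With the arrays centred on their median and no loess curve, the brighter probe gave 0.08 (limma adjusted p = 0.708). The sign of that probe thus depended on the scaling and its direction was not settled. That scaling also put the median of all genes at 0.10 instead of −0.02, so the turn of sign does not show a rise relative to other genes. CBFb, the subunit that stabilizes the binding of Runx proteins to DNA, had a ratio of 0.02 ± 0.27 (adjusted p = 0.927), which was −0.09 on its other probe. A target named Core-binding facto had a ratio of 0.12 ± 0.11 (adjusted p = 0.283). A splice-blocking morpholino need not lower the amount of a transcript, and the position of the probes relative to the affected exons is unknown, so these values do not measure how well the morpholino worked.

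The second comparison asked which transcripts differed between the morphants and the control pool. The largest rise was that of Histone H1 early e, an embryonic early-type linker histone, at 2.88 ± 0.27 on the log2 scale (SD, n = 4), or 7.34-fold (adjusted p = 0.0253), and its other probe gave 3.84. It was followed by Histone-lysine N-m at 2.45 ± 0.37 (5.45-fold), Trx at 2.13 ± 0.76 (4.36-fold) and the phosphatase PTP RL10B at 2.08 ± 0.63 (4.22-fold). The largest fall was that of a galectin-like protein (GALECTIN LIKE PROTE), a carbohydrate-binding protein, at −2.79 ± 0.81, or 0.145 of the control level (adjusted p = 0.0315), with −1.67 on its other probe. CARBONIC ANHYDRASE 14, an enzyme that hydrates carbon dioxide, fell to 0.192 of the control (−2.38 ± 0.34, adjusted p = 0.0253), with −2.16 on its other probe.

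In all, 274 of 5481 genes passed limma's test at an adjusted p under 0.05, of which 162 rose and 112 fell. Each of the 274 had 1 sign in both dye orientations and in all 4 cultures. The latter follows from the threshold, which a gene with a culture across 0 could not reach at n = 4. The median log2 ratio was 0.95 for the rises and −0.92 for the falls, and 71 rose and 47 fell at least 2-fold. The next rises were SPAN protein (4.03-fold), PROBABLE PHOSPH (3.76-fold), SIMILAR TO GLUTATHI (3.60-fold), ATP SYNTHASE BE (3.52-fold), G2/mitotic-specifi (3.50-fold), a Ubiquitin precursor (3.41-fold; 1.77 on the log2 scale, against 0.76 on its other probe) and Separase Caspase like (3.41-fold). On its other probe ATP SYNTHASE BE had a ratio of only 0.35 against 1.82 on the one tested. Separase, the protease that releases sister chromatids, gave 2.11 on its other probe. Further falls were those of the lectin ECHINOIDIN CK P (−1.90 ± 0.54), CERULOPLASM (−1.82 ± 0.70), EF1A (−1.80 ± 0.53), FB19 Serine thr (−1.70 ± 0.65) and the target of probe CUST_11963 (−1.65 ± 0.63). They also included Y51H7BR.5 Retrovirus (−1.63 ± 0.53) and the actin-binding peptide THYMOSIN BETA 31 (−1.60 ± 0.62), saturated on 1 of 8 arrays in the morphants and 2 of 8 in the control. The RNA-binding Quaking protein A fell too (−1.60 ± 0.26), with −0.49 on its other probe. The adjusted p of these genes lay between 0.0253 and 0.0458. Of 250 changed genes with a second usable probe, that probe had the opposite sign for 15 and a log2 change smaller by over 2 times for 50.

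The count of 274 depended on single cultures. It was 887 without culture 1 (355 rose, 532 fell), 1 without culture 2 and 0 without culture 3 or culture 4, where limma still gave 1219 and 1346 genes at an unadjusted p under 0.05 against 1933 with all cultures. It was also 0 with an intensity trend and robust variances in limma, with 2045 genes at that unadjusted level, and 56 with median centring in place of loess (49 rose, 7 fell), a scaling that put the median of all genes at 0.10 instead of −0.02.

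**Figure D1:**
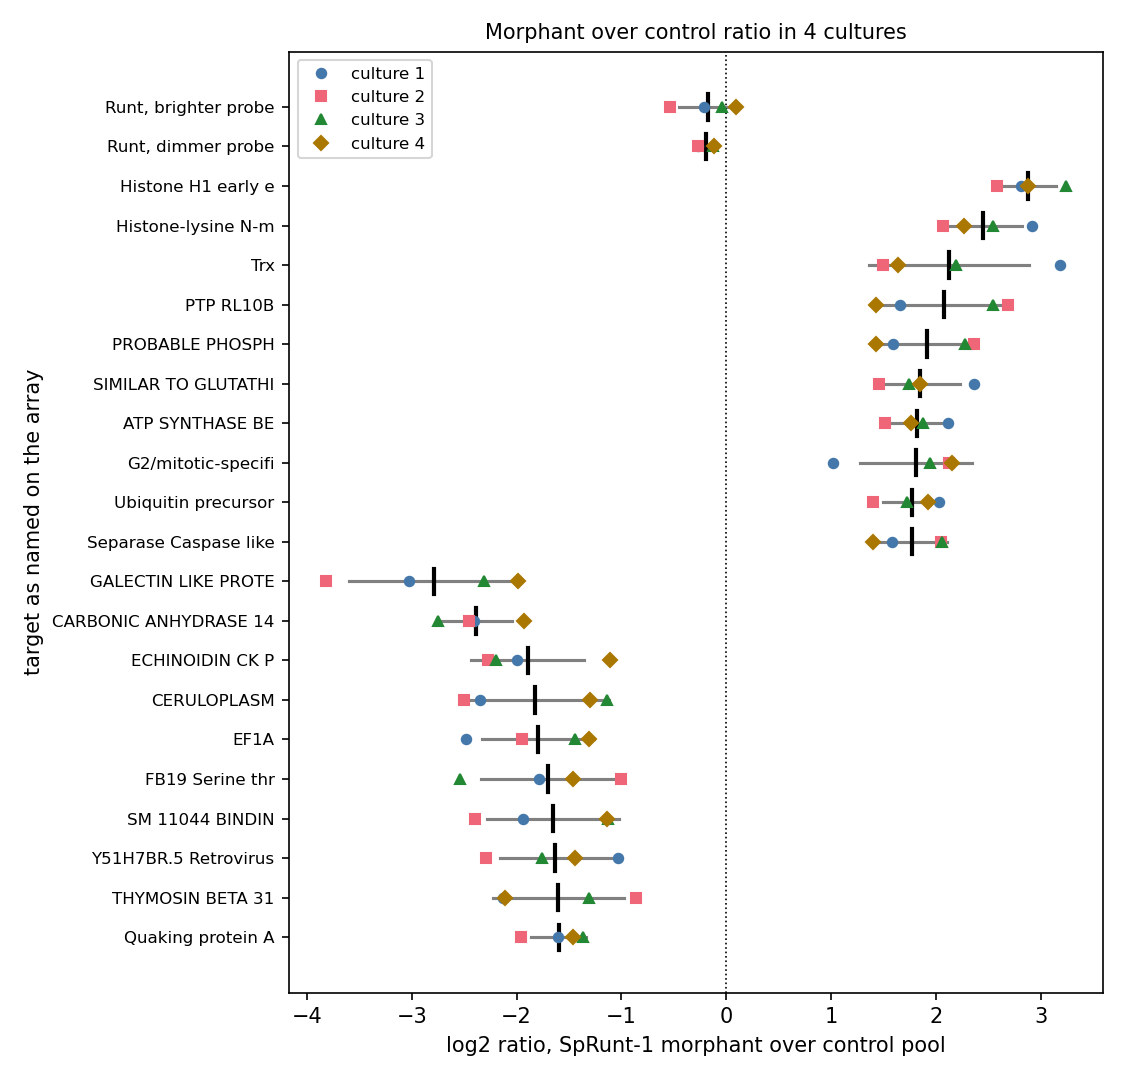
Log2 ratio of morphant over control pool (horizontal axis) for the 2 Runt probes and the 10 largest rises and 10 largest falls among passing targets that the rule took as named, which left out SPAN protein (2.01). Each marker is 1 culture (the mean of its 2 arrays), the black bar is the mean of the 4 cultures and the grey line is ± 1 SD. The Runt values lie near 0, from −0.54 to 0.09 on the brighter probe. Each of the other 20 genes has 4 cultures on 1 side of 0, which the rule required.

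The tests of 24 gene lists, fixed before the data were examined, asked which parts of the embryo's program moved. None of the 22 lists with at least 5 measured members passed limma's camera test (lowest adjusted p = 0.539), and none did with an estimated correlation (lowest adjusted p = 0.851). At an unadjusted p under 0.05 camera gave 1 list, the ribosomal proteins. The self-contained test fry passed 1 list for movement in 1 direction, cilia (adjusted p = 0.0382; 0.169, 0.117, 0.0742 and 0.0830 without culture 1, 2, 3 and 4, and 0.0890 with median centring), and 21 lists for changes in either direction. The test for either direction does not compare a list with other genes. Since 35.3% of all genes had an unadjusted limma p under 0.05, those 21 passes do not set the lists apart. The mean, the median and the direction of camera differed in sign for the early blastula, the late blastula to gastrula, the neurogenic and the stress lists. The 48 changed genes that the naming rule gave kept their direction under each of the 16 other settings that measured them (15 for Complement C3). Leaving out a culture or a dye orientation could not turn it, since these genes had 1 sign in all cultures and both orientations. Nor could quantile scaling of average intensities, which leaves ratios untouched, and the random block averages the same ratios. The kept direction therefore rests on the remaining settings. All 48 missed the threshold without culture 2, 3 or 4, and 35 did so with median centring. The ratio moved by over 1.5 times under at least 1 setting for 14 of them, for 9 of these most with Agilent's own log ratio. With that ratio FoxY had 3.79 instead of 1.73, COLLAGEN VIII A −2.70 instead of −1.19, Complement C3 −1.67 instead of −0.48 and 1 Ubiquitin precursor 1.97 instead of 0.90, so that their sizes are not settled. CARBONIC ANHYDRASE 14, CERULOPLASM, Pre-mRNA-splicing, UBIQUITIN CONJU and CYTOCHROME P450 2D28 had −3.28, −2.64, 1.48, −1.66 and 1.05. The mean of a gene's probes gave ATP SYNTHASE BE 1.08 and Histone H1 II 0.19, and median centring gave D6.1A Tetraspan 1.64, GALECTIN LIKE PROTE −2.20 and SPAN protein 2.60. Of the 15 other genes that the rule gave besides Runt, which did not pass, 10 passed under at least 1 other setting: Akt under 7, Synaptotagmin under 4, Wnt6 under 3, Blimp1, FoxA, Synaptotagmin- and 1 Chd under 2, and Akt c, Late histone H2A.2.1 and RPS9 PROTEIN under 1. Leaving out culture 1 was among these settings for Akt (−1.61, adjusted p = 0.0412), Blimp1 (−1.41, adjusted p = 0.0434) and FoxA.

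Among regulators of signalling and division, none of the 9 measured genes of Wnt signalling passed, over all genes or adjusted over the list alone. Nor did any of the 3 earlier reported Runt-1 targets that were matched by name. Others on that list, such as cyclin D, PKC1 and CyIIIa, were not matched to a target, so their change is not known. Wnt6, a secreted Wnt ligand, had a ratio of 0.72 ± 0.53 (SD, n = 4), above 0 in all cultures with an interval of 0.14 to 1.30, but its adjusted p was 0.104. WNT 4 PROTEIN had 0.40 ± 0.34 (adjusted p = 0.139). Wnt8 had −0.07 ± 0.07 (adjusted p = 0.439) on a probe well above background on only 2 of 8 arrays in each RNA. Blimp1, a zinc finger repressor of the endomesoderm, had −0.98 ± 0.97 (adjusted p = 0.155) with 0.33 in culture 1 and −2.02 in culture 2, and its other probe pointed the other way, at 0.76. Akt, a survival kinase, had −1.41 ± 0.62, below 0 in all 4 cultures, but missed the threshold (adjusted p = 0.0531). Akt c had −0.60 ± 0.34 (adjusted p = 0.0741). Of the 8 genes of Akt, PI3K, TOR and PKC signalling none passed over all genes, and 2 were lower adjusted over the list alone. In the cell cycle list 1 of 27 genes rose, and adjusted over the list alone 2 were higher and 1 lower. It was Skp2, a substrate receptor of a ubiquitin ligase (1.45-fold, limma adjusted p = 0.0283, with 0.16 on its other probe). The list missed a target named G2/mitotic-specifi (3.50-fold, with 1.64 on its other probe) because its name is shortened. Other targets with the same shortened name were not among the genes that passed. In the list completed with shortened names after seeing the data, 2 of 60 genes rose and none fell. In the apoptosis and DNA damage list 1 of 5 rose, over all genes and adjusted over the list alone. It was Separase Caspase like, which entered by the word Caspase in its name and need not be an apoptosis gene. Of the 2 members of Runx and partners, Runt and CBFb, neither passed, nor did either when adjusted over the list alone.

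Among the territories of the embryo, the 2 mesodermal lists held genes that fell. Erg, an ETS-family transcription factor that stands in both mesodermal lists, fell to 0.447 of the control (−1.16 ± 0.41, adjusted p = 0.0458). P19, a protein of skeletogenic cells, fell to 0.591 (−0.76 ± 0.23, adjusted p = 0.0441), and Complement C3, an immune protein of blastocoelar cells, fell to 0.718 (−0.48 ± 0.13, adjusted p = 0.0458), with the morphant RNA well above background on 7 of 8 arrays and log2 ratios of −1.67 to −0.36 over the other settings. Thus 2 of 10 skeletogenic genes and 2 of 6 pigment and blastocoelar cell genes fell and none rose. Adjusted over the list alone, 3 skeletogenic genes were lower and 2 higher, and 4 pigment and blastocoelar genes were lower and 1 higher. FoxY, a forkhead transcription factor, was the 1 of 21 endomesoderm regulators that rose (3.32-fold, 1.73 ± 0.18, adjusted p = 0.0253), over all genes and adjusted over the list alone, and its control signal was well above background on only 4 of 8 arrays, with log2 ratios of up to 3.79 over the other settings. ARYLSULFATASE B, whose family includes a marker of the aboral ectoderm, was the 1 of 23 aboral ectoderm genes that fell (−1.51 ± 0.51, adjusted p = 0.0430), again also adjusted over the list alone. None of the 8 oral ectoderm genes passed, over all genes or adjusted over the list alone; the targets named Chd, which entered by that symbol and need not be chordin, had −0.30 ± 0.13 (adjusted p = 0.0766) and 0.19 ± 0.05 (adjusted p = 0.111). None of the 9 neurogenic and apical plate genes passed over all genes, and 2 were higher and 1 lower adjusted over the list alone. Synaptotagmin, of synaptic vesicles, had 0.58 ± 0.26 (adjusted p = 0.0588). A target named Synaptotagmin- had −0.28 ± 0.05 (adjusted p = 0.0605), which was 0.15 with median centring.

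Of 5 measured targets named as tektins, filament proteins of ciliary microtubules, 2 rose. TEKTIN A1 rose 2.13-fold (1.09 ± 0.14, adjusted p = 0.0253) and TEKTIN B1 1.63-fold (0.71 ± 0.17, adjusted p = 0.0342; 0.15 on its other probe). The targets Tektin-1 - Bos, Tektin-3 - Homo and Tektin-B1 - S had 0.99, 0.50 and 0.17 (limma adjusted p = 0.147, 0.249 and 0.191). By its name Tektin-B1 - S may be the same gene as TEKTIN B1, whose rise then rests on 1 probe. The 2 that rose were the 2 of 22 genes of the cilia list that passed, of which 4 were higher adjusted over the list alone. Of 15 early blastula genes 3 rose and none fell, and adjusted over the list alone 6 were higher and 3 lower. The mean of the list (0.36) and its median (−0.00382, and 0.39 with median centring) differed in sign. The 3 that rose were Histone H1 early e, SPAN protein and D6.1A Tetraspan. SPAN protein, a protease of the blastula, rose 4.03-fold (2.01 ± 0.68, limma adjusted p = 0.0416), with 1.37 on its other probe. D6.1A Tetraspan (2.07-fold) is a tetraspanin that entered by the letters of its name. None of 8 late blastula to gastrula genes passed, over all genes or adjusted over the list alone. Among them Late histone H2A.2.1 had 0.42 ± 0.20 (adjusted p = 0.0672) and FoxA, a regulator of the endoderm, had 0.88 ± 0.81 (adjusted p = 0.141), with −0.16 in culture 1. Of 27 histones 2 rose, Histone H1 early e and Histone H1 II (1.79-fold, adjusted p = 0.0255), the latter with −0.46 on its other probe, and adjusted over the list alone 4 were higher and 2 lower. Most histone messages carry no poly(A) tail, and the RNA was amplified from oligo dT.

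Among housekeeping functions, protein turnover held changes in both directions. Of 87 proteasome and ubiquitin genes 4 rose and 3 fell, and adjusted over the list alone 12 were higher and 11 lower. The 3 targets named Ubiquitin precursor that the rule gave rose 3.41-fold, 2.49-fold and 1.87-fold (adjusted p = 0.0253, 0.0261 and 0.0458), whereas UBIQUITIN CONJU fell to 0.542 of the control (adjusted p = 0.0342). Of 28 genes of mitochondrial respiration ATP SYNTHASE BE and ATP synthase gamma rose, the latter 1.73-fold (0.79 ± 0.26, adjusted p = 0.0458), and adjusted over the list alone 5 were higher and 4 lower. None of 10 ribosomal proteins passed over all genes and 2 were lower adjusted over the list alone. Their median was −0.24, and 0.30 with median centring, a scaling that put the median of all genes at 0.10. RPS9 PROTEIN had −0.62 ± 0.29 (adjusted p = 0.0605), and RPL3 had −0.35 ± 0.10 (adjusted p = 0.0563), or 0.17 with median centring. Of 27 RNA splicing genes 2 rose and none fell, over all genes and adjusted over the list alone: 45KDA SPLICING FACTOR (1.96-fold, adjusted p = 0.0439) and Pre-mRNA-splicing (1.61-fold, adjusted p = 0.0458). Of 51 heat shock, stress and xenobiotic genes 3 rose and 1 fell, and adjusted over the list alone 4 were higher and 8 lower. CYTOCHROME P450 rose 2.59-fold (adjusted p = 0.0452), CYTOCHROME P450 2D28 rose 1.33-fold (adjusted p = 0.0458), HSP4 rose 1.36-fold (adjusted p = 0.0441) and Y17G9B.3 cytochrome P450 fell to 0.736 (adjusted p = 0.0486).

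In the extracellular matrix and adhesion list 2 of 38 genes rose and 2 fell, and adjusted over the list alone 5 were higher and 8 lower. COLLAGEN VIII A, well above background in the morphants on 6 of 8 arrays, fell to 0.437 of the control (−1.19 ± 0.25, adjusted p = 0.0255) and FIBRILLIN 1, a protein of microfibrils, to 0.482 (adjusted p = 0.0283), whereas LAMININ B1 CHAIN, of basement membranes, rose 1.85-fold (adjusted p = 0.0458) and DISINTEGRIN METALLO 1.46-fold (adjusted p = 0.0346). Of 58 genes of the actin cytoskeleton and motility 2 rose, Actin nonmuscle - (3.33-fold, 1.74 ± 0.36, adjusted p = 0.0253) and ACTIN CYTOSKELE (1.45-fold, adjusted p = 0.0458), and adjusted over the list alone 3 were higher. Of 17 transposable element and virus-like genes 1 rose, DNA pol (1.72-fold, limma adjusted p = 0.0458), which entered by its shortened name. Adjusted over the list alone 1 was higher and 1 lower. Y51H7BR.5 Retrovirus was matched neither to this list nor to the completed one. It fell (−1.63 ± 0.53, limma adjusted p = 0.0389), with −1.35 on its other probe.

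**Figure D2:**
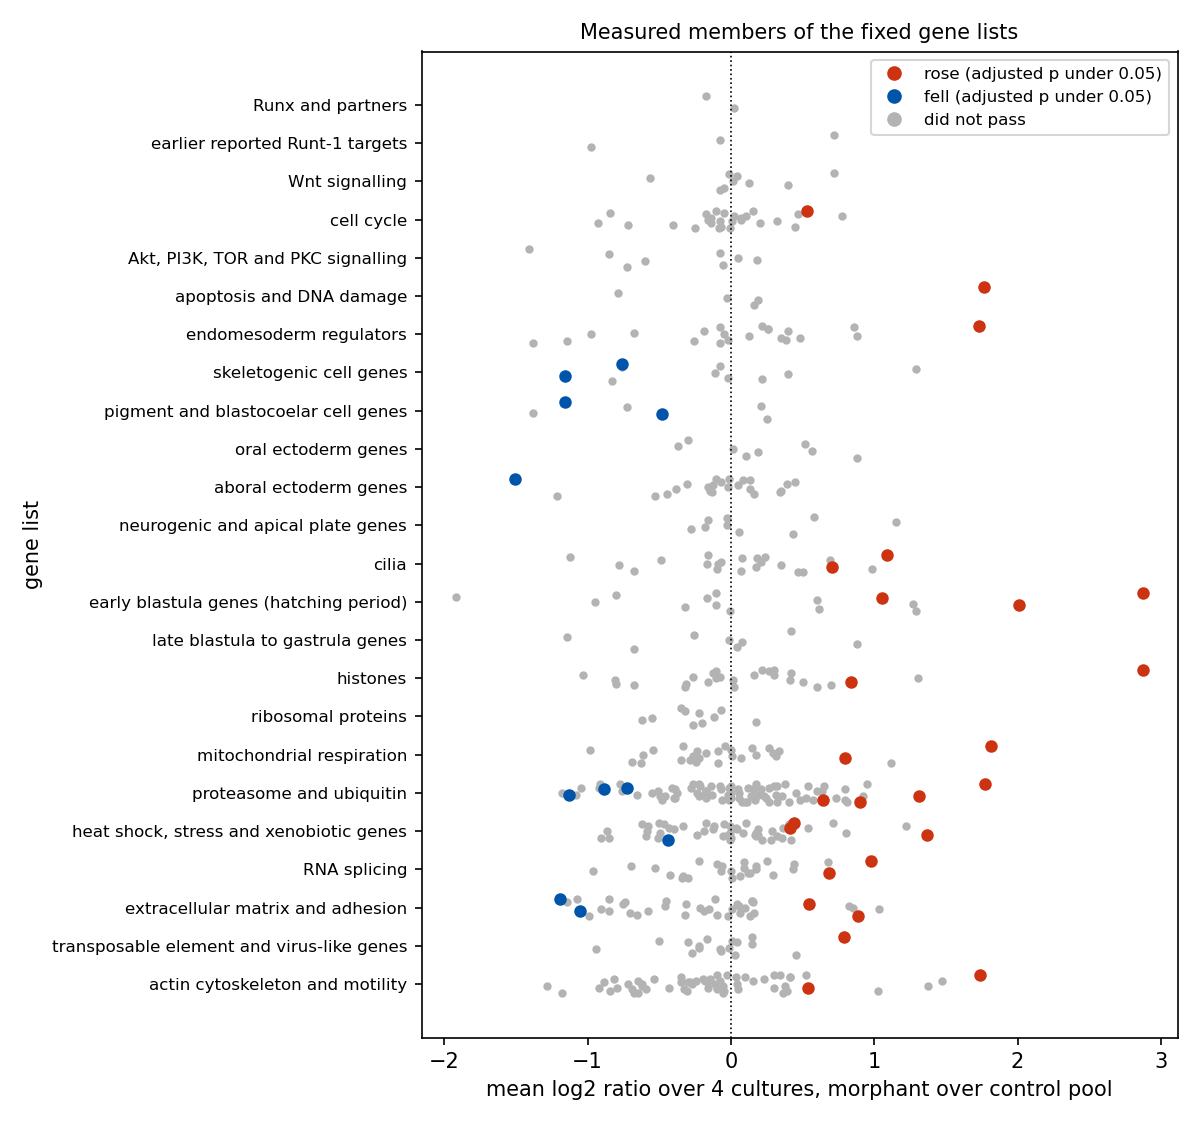
Mean log2 ratio of morphant over control pool over 4 cultures (horizontal axis) for each measured member of the 24 gene lists (vertical axis); points are spread vertically only for legibility. Red points rose and blue points fell at an adjusted p under 0.05 over all genes, and grey points did not pass. Most members of every list are grey, and the largest value is that of Histone H1 early e at 2.88.

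The third comparison asked whether the ratio to the common pool was the same in the 4 cultures. It differed for 3336 of 5439 genes measured on all arrays (61.3%; limma F test with the dye as a term, adjusted p under 0.05), against a residual that comes from arrays of the same RNA, so that the test compares these RNA samples and not populations. Blimp1 was among them, with a span from −2.02 to 0.33, as was Akt, from −2.26 to −0.80. Skp2 and TEKTIN A1 were not (adjusted p = 0.758 and 0.365 in the same F test). No culture was set against its own untreated embryos. Differences in response and baseline differences between the cultures therefore cannot be told apart in these ratios. Culture 1 correlated least with the mean of the other cultures across genes (r = 0.428), while cultures 2, 3 and 4 had 0.719, 0.702 and 0.675, and genes are not independent replicates. Ratios of at least 2-fold were seen for 327 genes in culture 1, 940 in culture 2, 579 in culture 3 and 446 in culture 4. Of these, 196, 633, 269 and 222 were lower in the morphants. The 2 arrays of 1 RNA correlated at 0.890 to 0.961, and 179 of the changed genes (66.5% of those tested in both ways) also had ratios that differed between cultures.

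The cultures share 1 control pool. Their ratios correlated across genes at a mean of 0.506 with a covariance of 0.192, and 44.4% of genes had 1 sign in all cultures, whereas 20 simulations of unchanged cultures against a pool of their own RNA gave −0.254, −0.0371 and 11.4%. In that simulation the pool departs from the mean of its cultures only by noise of the size seen between arrays. The pool cannot be divided, and part of the excess may come from a larger departure. The controls were not injected, so the effects of the morpholino and of injection cannot be told apart, and with 1 pool the tests leave out the control's own spread.

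**Figure D3:**
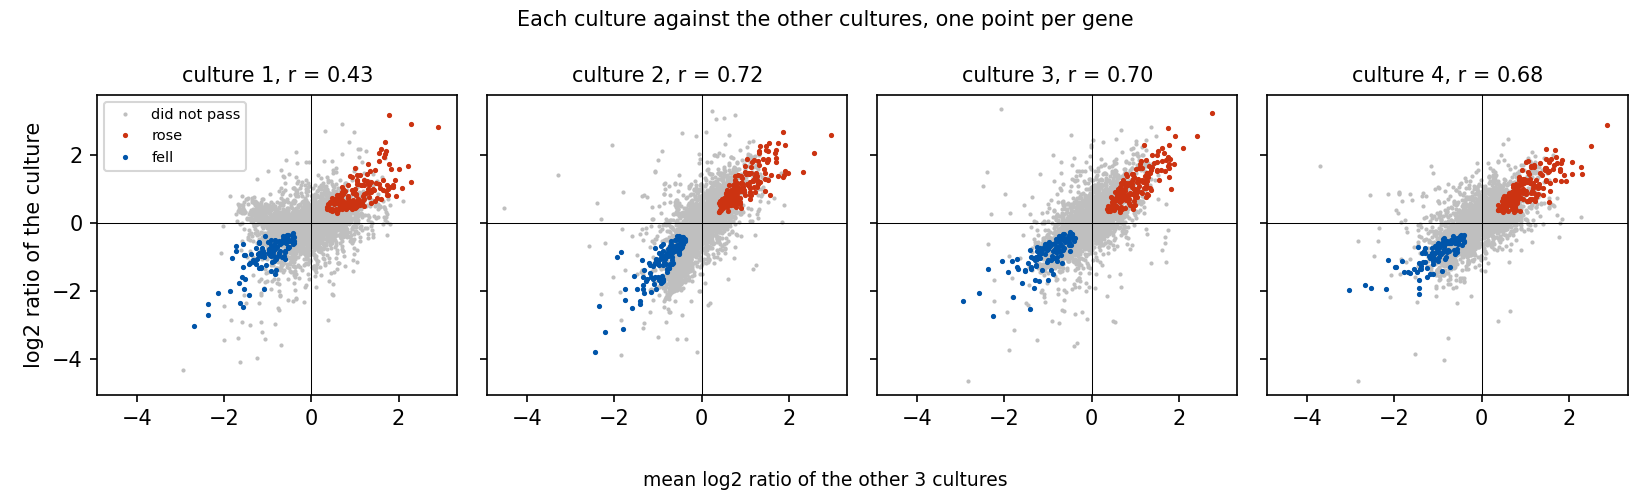
Log2 ratio of each culture (vertical axis) against the mean log2 ratio of the other 3 cultures (horizontal axis), with 1 point per gene measured in all cultures. Red points rose and blue points fell in the test of the mean over the 4 cultures, and grey points did not pass. The correlation is 0.428 in culture 1 and 0.675 to 0.719 in the others.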

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

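The test of the reliability of culture 1 was chosen only after its result was seen. Among 70 results, 4 had 1 culture far from the other 3, and chance gives about 1 in 20 groups. Synaptotagmin had a log2 ratio of 0.97 in culture 3 against 0.41 to 0.50 in the others. RPS9 PROTEIN had −1.06 in culture 2 against −0.53 to −0.43. ATP synthase gamma had 0.40 in culture 1 against 0.90 to 0.96.

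The fourth is culture 1, whose ratios correlated across genes at 0.428 with the mean of the other cultures, while the others had 0.675 to 0.719. The tables argue against noise of its arrays as the whole source, since the correlation corrected for the reliability of its dye-swap pair was 0.437 against 0.696 to 0.726 in the others. They argue against the normalization too, since the highest correlation of culture 1 under 5 other scalings was 0.431, where the others had 0.632 to 0.720. What stays open is that its parents, its stage at collection, the injection or its share of the pool may have differed, and neither a biological difference between mating pairs nor these was tested. For the count of 274 changed genes, 1 of the 8 patterns of turned signs (the real one) gave as many, the highest other gave 0, and 8 patterns are too few for a share under 0.05.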

How the results depend on the processing

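The completed lists were chosen after seeing the data. Signal over background limits the dimmer probes. The number of changed genes was 274; within 1.5 times of it were no background subtraction, only 1 dye orientation, the mean of a gene's probes, a 1.5-fold minimum and quantile scaling of average intensities, which leaves ratios untouched and so tests nothing. It was 796 with normexp without offset, 839 with Agilent's log ratio, 581 with the authors' table, 56 with median centring, 180 without a filter and 448 with a strict one, 1269 with culture as a random block, 509 over all probes, 1224 at an adjusted p under 0.10 and 0 with trend and robust variances in limma (2045 at an unadjusted p under 0.05). Leaving out a culture gave 887 (culture 1), 1 (culture 2) and 0 (culture 3 or 4, with 1219 and 1346 at that unadjusted level). Of the rises, the share was 59.1%, 87.5% with median centring, 45.1% with the random block and 48.7% at 0.10. Of the 162 rises and 112 falls, 143 and 93 were also called with Agilent's ratio, 31 and 7 with median centring, and 161 and 108 with the random block. The median of all genes was −0.02, −0.11 with Agilent's ratio, −0.10 with the strict filter and 0.10 with median centring. With median centring Runt turned to 0.077 on its brighter probe (limma adjusted p = 0.708), Synaptotagmin- to 0.15 and RPL3 to 0.17. CBFb turned to −0.068 in the authors' table, −0.090 with the morphant in Cy5 and −0.038 with the mean of its probes, and leaving out 1 culture gave −0.093 (without culture 2) to 0.107, with −0.018 without culture 3. The number of lists passing was 1 with fry and 1 with completed lists instead of 0, and 4 with fry on completed lists. The causes were not tested, apart from the wider threshold. The genes whose ratio differed between cultures, 3336, numbered 2568 to 3915 under the 12 alternatives run.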

Other observations

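The completed lists, the estimated correlation of the ribosomal list and the comparison of early with late genes were chosen only after the results were seen. Once shortened names were assigned to the lists, 5 of 54 RNA splicing genes rose and none fell, and 7 were higher adjusted over the list alone. Pre mRNA splicing fac rose 3.39-fold (1.76 ± 0.40, SD, n = 4, adjusted p = 0.0255) and Small nuclear r 2.99-fold (1.58 ± 0.34, adjusted p = 0.0253), each with a like value on its other probe, 1.87 and 1.54. U1 SMALL NUCLEA rose 1.95-fold (adjusted p = 0.0333). The list did not pass camera (adjusted p = 0.473, and 0.904 with an estimated correlation), and its median of 0.00593 turned sign under 5 of 15 settings, to −0.00249 without background subtraction among them.

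Of 18 pigment and blastocoelar genes 3 fell and none rose, over all genes and adjusted over the list alone. The falls now included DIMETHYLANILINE, the start of the name of the flavin monooxygenases, at −1.40 ± 0.32 (limma adjusted p = 0.0270), with −0.61 on its other probe. Of 19 skeletogenic genes 3 fell and none rose, with 6 lower and 2 higher adjusted over the list alone, now with 41 KD SPICULE M, a spicule matrix protein, at −0.50 ± 0.13 (adjusted p = 0.0458). Of 14 Wnt signalling genes 1 fell and none rose, with 1 lower and 1 higher adjusted over the list alone. It was 1 of 2 targets named sFRP, a secreted inhibitor of Wnt ligands, which fell to 0.664 of the control (adjusted p = 0.0389), with −0.12 on its other probe. Of 78 stress genes 5 rose and 1 fell, with 7 higher and 9 lower adjusted over the list alone and a median of −0.02, and Thioredox and Metallothione rose 2.22-fold and 1.69-fold (adjusted p = 0.0283 and 0.0253). Of 16 early blastula genes 2 rose and 1 fell, with 5 higher and 1 lower adjusted over the list alone, and VERY EARLY BLASTULA fell to 0.484 (adjusted p = 0.0346). Fry passed 4 completed lists for movement in 1 direction, each at an adjusted p of 0.0495: cilia and early blastula genes towards higher values, skeletogenic and transposable element genes towards lower ones. None of the 4 passed camera (adjusted p = 0.473, and 0.904 with an estimated correlation), or fry without any 1 culture (adjusted p from 0.0754 to 0.193) or with median centring (0.112 to 0.997).

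Of 110 ribosomal protein genes 7 fell and none rose, such as 40S RIBOSOMAL PR at −1.27 ± 0.23, and the list passed camera (median −0.24, adjusted p = 0.00707; from 0.000599 to 0.932 over the alternatives, and 0.0585 without culture 2), although its median was 0.18 with median centring and its adjusted p was 0.904 with an estimated correlation. These are bright genes, and their brightness stays open as a source, since the median lay at percentile 2.62 of 10000 lists matched on intensity, at the edge of their 95% range of −0.24 to 0.04. The loess curve stays open too, with percentile 20.1 among matched lists under median centring. The 95% range of those lists was 0.09 to 0.45, so lists of like brightness lay above 0 under that scaling. Members that move together between cultures may account for the call, which the adjusted p of 0.904 leaves undecided, because the medians were below 0 in all cultures (−0.07, −0.43, −0.17 and −0.23). At percentiles 19.9, 0.17, 8.48 and 0.44 of matched lists, cultures 2 and 4 stood lower than the others.

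Rises of Histone H1 early e and SPAN protein, against a fall of VERY EARLY BLASTULA (−1.05), raise the hypothesis that the morphants may have been developmentally behind the pool. The other 13 members of the completed early list did not pass. The mean of the 15 early blastula genes exceeded that of the 8 late blastula to gastrula genes by 0.44 (0.36 against −0.08), at percentile 97.0 of 10000 matched pairs of lists, inside their 95% range of −0.55 to 0.46. With the completed early list of 16 genes, without tetraspanins matched by letters, the difference was 0.53, at percentile 99.2 and above the range of −0.51 to 0.44. Both early means include Histone H1 early e (2.88), the largest rise, and the difference without it was not tested. Its rise carries a further limit, as most histone messages lack a poly(A) tail and the RNA was amplified from oligo dT. The difference of medians was −0.02 with the fixed lists (percentile 53.4) and 0.19 with the completed ones (percentile 86.8), inside the matched range in both. A delay stays undecided, as the hypothesis came from members of the early list, 1 passing member of the completed list fell, the mean and the median differ, and the late list had a median of 0.02.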
